A study of Mus musculus with 4 samples.

How the data were processed

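The data are expression arrays of microglia isolated from mouse brain, 4 arrays in all: PBS and OVA at P30 and PBS and OVA at P70, with 1 array per group. Per the series design, microglia were collected 1 day after intranasal challenge and material of 4 samples was pooled per group. Per the labels' protocols, total RNA was extracted with TRIzol and a column kit, amplified with the GeneChip WT Pico reagent kit and labelled with biotin. The submitters' processing notes name RMA and Affymetrix Expression Console 1.4.1 without saying what each did. Scanner files were not used here.

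The deposited values are intensities on a linear scale, 1 per probe set and array, already normalized and summarised by the authors. RMA itself writes log2 values, whereas the lowest deposited values were between 8.35 and 9.82 and the highest between 873707 and 999952, so the values were taken as linear. How the arrays were scaled to each other is not given in the sources used here, nor is the genome build. The brightest probe sets of an array shared nearly one value: 98 probe sets in PBS and 109 in OVA at P30, and 19 in PBS and 13 in OVA at P70, lay within 0.01 log2 units of the array's highest value, which was 19.88, 19.74, 19.93 and 19.93 in that order. A gene at this limit carries the difference between the limits, -0.14 for OVA minus PBS at P30, and not a measured difference. Above log2 14, 7 expressed genes had 4 values that followed the limits within 0.02: COX1, Cst3, Cx3cr1, Itm2b, Rps23-ps, Serinc3 and mt-Rnr1. Between 2 arrays, genes at log2 12 or more whose difference equalled that of the limits within 0.0001 were counted as capped: 9 for OVA minus PBS at P30, 6 at P70, and 8 in PBS and 10 in OVA for age. This count was added after the values were seen. It matches differences alone, and a gene counted so need not lie at the limit itself: Cx3cr1 had a mean level of 18.3.

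From the deposited intensities, log2 values were computed and used with no further normalization. Of 65956 probe sets, 30604 carried 1 gene symbol in the platform annotation, 2146 carried several and 33206 none here; names were taken from those with 1 symbol. The symbols of 827 probe sets were updated through their Entrez ID with a RefSeq gene table of the assembly GRCm38.p6, used for names alone. Predicted genes, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments were left out (12736 probe sets), of which 172 were recognised as small RNAs by symbol patterns added after the data were seen. Of the 17629 genes kept, 195 had more than 1 probe set and were represented by the brightest. Expressed genes were those whose mean over the 4 arrays was at or above the median of such means, 8815 genes.

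Differences are log2 differences between 2 arrays: OVA minus PBS at each age and P70 minus P30 in each treatment. With 1 array per group there was no spread within a group to test against. A fit adding treatment and age would take the difference between the OVA effects, itself of interest, as its only residual degree of freedom, and was not made. Genes were therefore counted at a difference of at least 1.5-fold. Named genes followed a rule: the 12 highest and 12 lowest differences in each OVA comparison, the 5 highest and 5 lowest in each age comparison, the 6 highest and 6 lowest differences between the OVA effects, and for each list described up to 4 members with the largest difference and up to 2 with the highest level. Genes from families of near-identical copies are named as uncertain.

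A set of 28 gene lists was fixed, 16 of programmes and 12 of cell types other than microglia that a brain isolate can hold. The lists name 735 symbols, of which 641 were found among the genes kept and 392 were expressed; 17 expressed genes stood in more than 1 list. For each list with at least 5 expressed members, the median difference was placed as a percentile among 10000 random lists drawn from expressed genes in the same 20 bins of mean level (seed 11). The percentile describes these arrays and is not a p-value. The comparisons, lists, rule for named genes, thresholds and alternatives were chosen before the data were examined, except where stated.

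The procedure was tested on simulated data for the P30 OVA comparison with 8815 genes. Of 200 genes changed 2-fold under noise of 0.16 log2 units (SD), 100% were called in the right direction, and 2 unchanged genes were called; with 3-fold changes 100% and 0. Lists of 20 genes shifted by 0, 0.1 and 0.2 log2 units lay outside the central range in 4%, 58.5% and 99% of 200 draws. Such noise leaves out differences between animals and between isolations, and genes that vary together. It was also smaller than the SD of the observed P30 differences across genes (0.21). The 2 unchanged genes called are therefore no estimate of false calls in the data.

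Alternatives covered the filter on dim genes (none, stricter, or on the highest array), the normalization (median centring, quantile normalization, or lowess centring along the level with a fraction of 0.3), the mean of a gene's probe sets, all probe sets with 1 symbol, a 2-fold threshold, cell type markers left out, unmatched random lists, genes of several lists left out and the list mean. The alternative with all probe sets of 1 symbol also kept the predicted, small-RNA, receptor and segment genes otherwise left out. It still took the brightest probe set per symbol, and its floor was set anew. An alternative with the symbol patterns as first written and one with cell type markers left out of the programme lists were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.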

Results

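Microglia, the resident macrophages of the brain, were isolated from whole brains of male C57BL/6J mice and profiled on 1-colour expression arrays. The mice had received PBS (the control group) or OVA (the allergy group), and microglia were collected 1 day after an intranasal challenge at postnatal day 30 (P30) or 70 (P70). Material of 4 samples was pooled per group and each of the 4 groups was hybridised to 1 array. There were therefore no replicates, no test was made, and every difference given here is a difference between 2 arrays whose number limits the precision. Levels and differences are in log2 intensity. Of 17629 named genes, 8815 had a mean level at or above the floor of 7.18 and are called expressed. The median deposited intensity over all probe sets was 131 in PBS and 132 in OVA at P30, and 111 in PBS and 105 in OVA at P70. Across the expressed genes, the PBS and OVA arrays correlated at r = 0.990 at P30 and r = 0.989 at P70, and the P70 and P30 arrays at r = 0.946 in PBS and r = 0.926 in OVA; genes are not independent replicates.

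The comparison at P30 asked how microglia of the allergy group differed from controls at the younger age. Immediate early genes were much higher in OVA, and several genes of neutrophils were lower. Dusp1, a phosphatase that inactivates MAP kinases, stood 9.91-fold higher in OVA (14.83 against 11.52 in PBS). The AP-1 components Jun and Fos were 3.98-fold and 3.88-fold higher, Fos from a PBS level just under the floor (7.16), and the chemokine gene Ccl3 was 4.07-fold higher. On the other side, Retnlg, Ngp, S100a9, S100a8, Camp and Mmp8, all expressed by neutrophils, were between 2.48-fold and 3.86-fold lower. Of the 8815 expressed genes, 57 were at least 1.5-fold higher and 78 at least 1.5-fold lower in OVA, which is 1.53% of them; 16 were at least 2-fold higher and 16 at least 2-fold lower. After quantile normalization, 97 were at least 1.5-fold higher and 113 lower.

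The other genes with the largest positive differences at P30 were the linker histone H1f2 (2.05), Ttr (1.87), Btg2 (1.71), Btg1 (1.53), Rhob (1.35), Zfp36l1 (1.29) and Zfp36 (1.27), with Rgs1 2.63-fold higher. Btg1 and Btg2 are antiproliferative genes, Rgs1 regulates G-protein signalling, and Zfp36 and Zfp36l1 encode proteins that destabilise mRNA. Ttr, the thyroid hormone carrier that the choroid plexus secretes, was at 7.45 in PBS and 9.32 in OVA. The remaining genes with the largest negative differences were Naip6 (-2.04), Clec7a (-1.71), ND2 (-1.57), Hba-ps4 (-1.16), Eola1 (-1.13) and Ccl6 (-1.11). Clec7a encodes the beta-glucan receptor dectin-1 and ND2 a mitochondrially encoded subunit of complex I. Naip6 and the alpha-globin pseudogene Hba-ps4 have near-identical copies, so their signals are uncertain.

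Among the 21 fixed gene lists with at least 5 expressed members, 7 had a median OVA minus PBS difference at P30 outside a central range. That range was the central 95% of 10000 random lists of the same size and expression level. Of 21 such random lists, 1.05 would be expected outside it. Members of 1 programme or cell type can vary together, which random lists leave out, so 1.05 is no baseline for chance. The immediate early list stood above all of its random lists, with a median of 1.13: 9 of its 14 expressed members were at least 1.5-fold higher and none lower. Dusp1 (3.31), Jun (1.99), Fos (1.96) and Btg2 (1.71) led it, and its brightest members were Dusp1 and Rhob. The neutrophil list stood below all of its random lists, with a median of -0.71 and 8 of 15 members at least 1.5-fold lower. Retnlg went from 10.81 in PBS to 8.86 in OVA, Ngp from 15.08 to 13.33, S100a9 from 14.13 to 12.49 and S100a8 from 13.38 to 11.85. The inflammatory cytokine and NF-kB list had a median of 0.13 (percentile 99.99), with 6 of 22 members at least 1.5-fold higher. Ccl3 (2.03), Il1a (0.76) and Ccl12 (0.74) were higher and the lipopolysaccharide co-receptor Cd14 (-0.79) was lower; the brightest members were Cd86, which was lower in OVA by 0.40 log2 units, and Il1a. With a stricter filter that kept brighter genes alone, the median of this list was -0.012 and no longer stood apart.

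Smaller downward shifts were seen in 4 other lists at P30. The disease-associated microglia list, genes known to be raised in microglia around amyloid plaques, had a median of -0.17 (percentile 0.105) and 4 of 25 members at least 1.5-fold lower: Clec7a (-1.71), Ccl6 (-1.11), Lyz2 (-0.93) and Lilrb4a (-0.62). Of the 25 members, 8 also stand in another list, and the arrays do not show which cells carried these genes. The lysosome and autophagy list had a median of -0.14 (percentile 0.440) with none of its 31 members at least 1.5-fold lower, and Lipa (-0.56), Atp6v1h (-0.51) and Ctsc (-0.49) as its lowest. The border-associated macrophage list had a median of -0.15 (percentile 1.27), led by Ms4a7 (-0.58) and Mrc1 (-0.46). The complement and phagocytosis list had a median of -0.13 (percentile 1.33), with Cd68 (-0.80) and Fcgr4 (-0.61) as the 2 of 33 members at least 1.5-fold lower. Each of these 4 medians lay inside the central range under at least 1 other setting. The upper limits of the 2 P30 arrays differed by 0.14 log2 units, lower in OVA, but no member of these 4 lists was counted as capped between them.

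The other tested lists lay inside the central range at P30. Their medians were -0.11 for homeostatic microglia, -0.11 for cholesterol and lipid efflux, -0.098 for antioxidant and iron handling, -0.080 for glycolysis and hypoxia, -0.074 for type 2 and alternative activation, -0.069 for glucocorticoid response, -0.065 for antigen presentation and -0.036 for oxidative phosphorylation. Medians of 0.0070 for interferon response, 0.017 for ribosomal protein, 0.017 for monocyte, 0.057 for cell cycle, 0.071 for endothelial and mural and 0.079 for T and NK cell markers completed the set. Without its capped members Cst3, Cx3cr1, Selplg and Sparc, the homeostatic list had a median of -0.076. The glucocorticoid response list, which also holds Dusp1, had a mean of the opposite sign, 0.31; the means of the monocyte (-0.012) and endothelial (-0.059) lists also had the opposite sign. Lists with fewer than 5 expressed members were not ranked: medians were -0.043 for B cell, -0.067 for mast cell, basophil and eosinophil, 0.037 for astrocyte, 0.010 for oligodendrocyte lineage and 0.047 for neuron markers. Ttr was the sole expressed gene of the ependymal and choroid plexus list, and Slc25a37 (-0.18) that of the erythroid list.

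The comparison at P70 asked the same of the older mice. Genes of border-associated macrophages and of type 2 responses were higher in OVA, and so were some genes of antigen presentation. H2-Eb1 and H2-Ab1, which encode chains of the class II major histocompatibility complex, were 4.61-fold and 3.27-fold higher, reaching 14.40 and 14.76 in OVA. Pf4 and Ms4a7, both markers of macrophages at the borders of the brain, were 3.91-fold and 3.84-fold higher. Ttr had the largest difference of the expressed genes, 17.3-fold, from 7.90 in PBS to 12.02 in OVA. The chemokine receptor gene Cxcr4 was 3.70-fold lower, at 9.50 in PBS and 7.61 in OVA.

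At P70, 353 expressed genes were at least 1.5-fold higher and 109 at least 1.5-fold lower in OVA, and 42 were at least 2-fold higher and 16 at least 2-fold lower. The median difference of all expressed genes was 0.091, and it was larger among bright than among dim genes. The excess of higher genes depended on it: 76.4% of the differing genes were higher as deposited, 52.3% (202 higher, 184 lower) after centring each array on its median, 50.9% after centring along the level and 49.8% (103 higher, 104 lower) after quantile normalization, which left the P70 total near that of P30. With all probe sets of 1 symbol the balance turned, to 38.8% (630 higher, 995 lower). That setting brought back the predicted, small-RNA, receptor and segment genes, for 15071 expressed genes, and still used 1 probe set per symbol. The other genes with the largest positive differences were Hba-ps4 (2.02), the ribosomal RNA gene Rn28s1 (1.79), Clec4b1 (1.58), Emp3 (1.43), Clec12a (1.42), Hcar2 (1.34) and Cd36 (1.32). Clec4b1 and Clec12a encode C-type lectin receptors, Hcar2 a receptor for hydroxycarboxylic acids and Cd36 a scavenger receptor. After Cxcr4, the largest negative differences belonged to Ttll2 (-1.58), Kprp (-1.53), the neutrophil collagenase gene Mmp8 (-1.46) and Naip6 (-1.30). The 3 genes Astx1a, Astx1b and Astx1c had identical values (-1.23), followed by Klk1b8 (-1.17), Speer4d (-1.16), Mup-ps18 (-1.14) and Spin2f (-1.08); all 7 belong to families of near-identical copies and are uncertain. Ttll2 (6.96), Kprp (6.07) and Klk1b8 (6.75) were under the floor in OVA and Cd36 (6.88) in PBS, so the sizes and ranks of their differences are uncertain as well.

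At P70, 6 of the 21 lists lay above the central 95% of random lists and none below. The border-associated macrophage list stood above all of its random lists, with a median of 1.00 and 6 of 11 members at least 1.5-fold higher. Pf4 went from 9.51 in PBS to 11.47 in OVA, Ms4a7 from 8.82 to 10.77, Dab2 from 8.27 to 9.58 and Cd209a from 9.91 to 11.21, whereas Maf, the brightest member, differed by 0.30. The type 2 and alternative activation list also stood above all of its random lists, with a median of 0.54 and 6 of 15 members at least 1.5-fold higher. The mannose receptor gene Mrc1 (1.06), which the border macrophage list also holds, the IL-13 receptor gene Il13ra1 (0.74), the chemokine gene Ccl24 (0.72) and the transcription factor gene Stat6 (0.68) were its largest, and Fcer1g, its brightest member, differed by 0.27. Of the 15 type 2 members, 3 also stand in another list, and the arrays do not show which cells carried these genes. The inflammatory cytokine and NF-kB list had a median of 0.27 (percentile 99.83) with 6 of 22 members at least 1.5-fold higher, led by Ccl12 (1.21), Ccl3 (0.99), Nlrp3 (0.84) and Ccl4 (0.75).

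The antigen presentation list had a median of 0.31 at P70 (percentile 98.4), and 4 of its 17 members were at least 1.5-fold higher: H2-Eb1 (2.21), H2-Ab1 (1.71), H2-Aa (1.02) and H2-DMb1 (0.76). These 4 belong to the class II pathway, of which H2-Oa (0.42) and H2-DMa (0.28), looked up after the values were seen, did not reach 1.5-fold; its brightest members Ctss and B2m differed by 0.031 and 0.12. The monocyte list had a median of 0.30 (percentile 99.2), with S100a4 (1.16) and Treml4 (0.97) at least 1.5-fold higher, Ms4a4c at 0.55 and Ccr2 at 0.48; its brightest member, Ly6c2, differed by 0.046. The disease-associated microglia list had a median of 0.26 (percentile 98.3), and Clec7a (1.00), Lilrb4a (0.78), Cst7 (0.76) and Itgax (0.69) were the 4 of 25 members at least 1.5-fold higher. These 3 lists came inside the central range after centring along the level (medians of 0.13, 0.16 and 0.073) and after quantile normalization (0.092, 0.13 and 0.045). Centring left H2-Eb1 at 2.02 and H2-Ab1 at 1.53.

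The remaining lists lay inside the central range at P70. Complement and phagocytosis had a median of 0.24 (percentile 97.1) with 6 of 33 members at least 1.5-fold higher, among them Cd36 (1.32), Rac2 (0.77), C1qb (0.74) and Fcgr4 (0.73). Between the 2 PBS arrays, C1qb differed by just as much as their upper limits did, so its difference is uncertain. The 2 P70 arrays had the same limit, so the lower PBS value of C1qb was not at that limit itself. The neutrophil list had a median of 0.041 and a mean of -0.14, with Mmp8 (-1.46) and Retnlg (-0.85) lower. The immediate early list had a median of 0.14 and none of its members was at least 1.5-fold higher, Dusp1 standing at 0.55; it lay above the central range after centring along the level (0.14) and after quantile normalization (0.12). Medians were 0.20 for homeostatic microglia, 0.18 for glucocorticoid response, 0.16 for interferon response, 0.16 for cell cycle, 0.15 for ribosomal protein, 0.15 for cholesterol and lipid efflux, 0.14 for lysosome and autophagy, 0.13 for oxidative phosphorylation, 0.12 for antioxidant and iron handling, 0.082 for glycolysis and hypoxia, -0.0053 for T and NK cell and -0.12 for endothelial and mural markers. Lists too short to rank had medians of 0.18 for B cell, -0.28 for mast cell, basophil and eosinophil, 0.061 for oligodendrocyte lineage, -0.091 for neuron and 0.47 for astrocyte markers, the last with Ndrg2 (0.89) and Slc1a3 (0.70) among its 4 members. Slc25a37 of the erythroid list differed by 0.24.

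**Figure D1:**
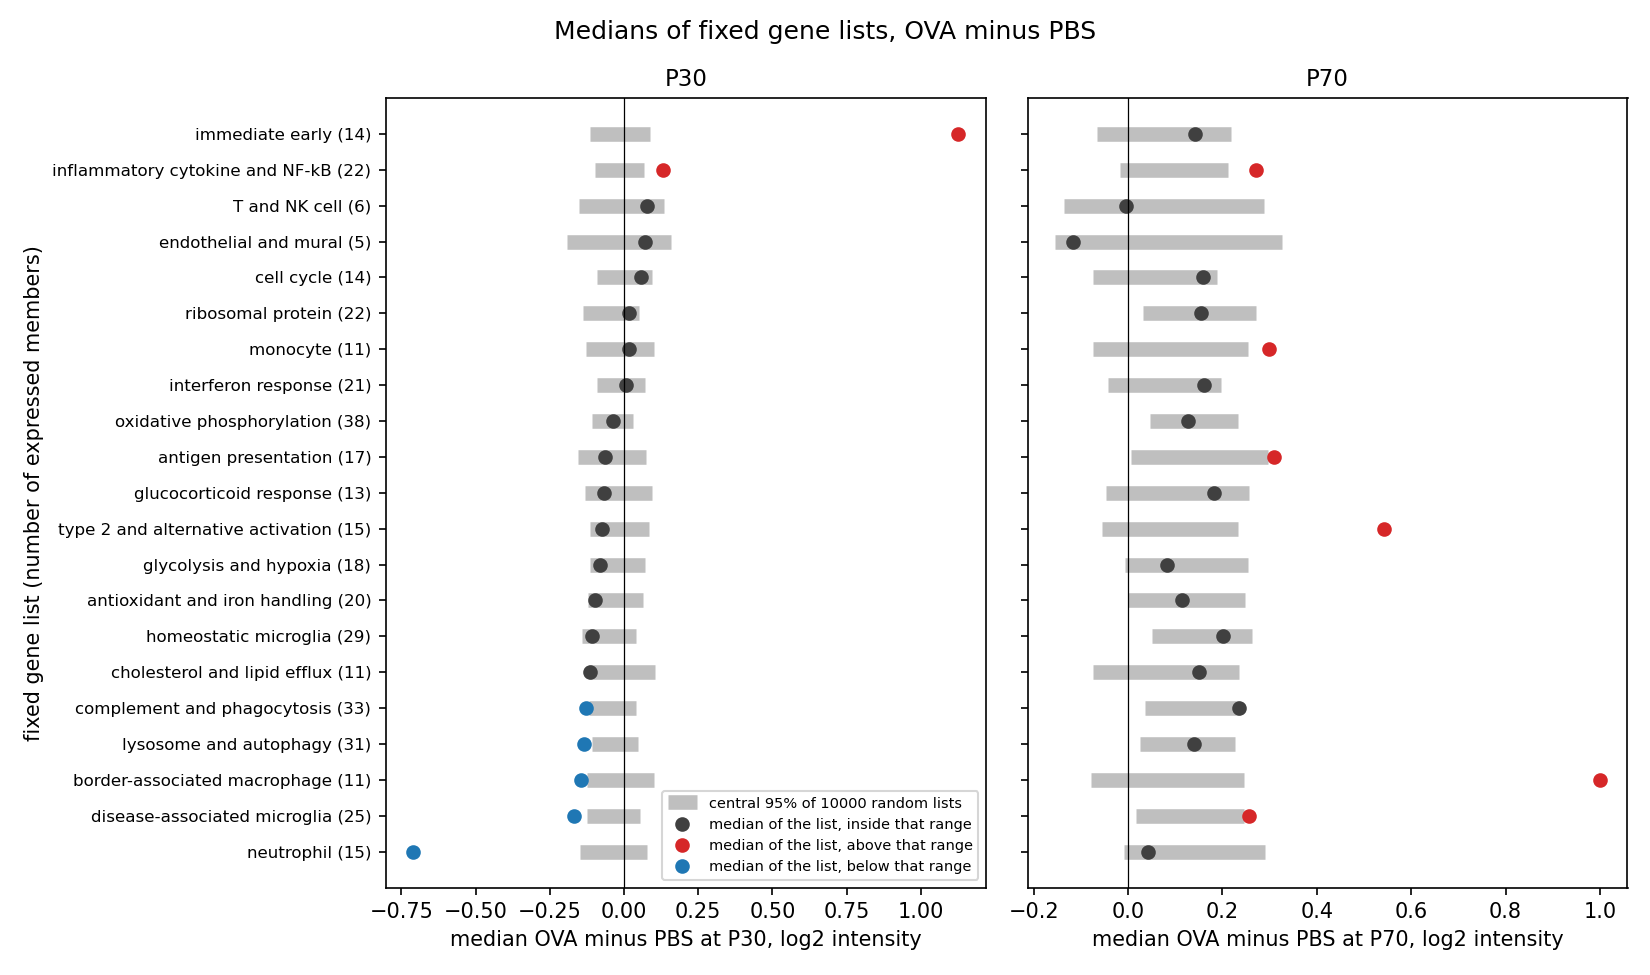
Median OVA minus PBS difference in log2 intensity (x axis) of each ranked gene list (y axis, number of expressed members in parentheses) at P30 (left) and P70 (right); points are medians and grey bars the central 95% of 10000 random lists of matched size and level. At P30 the immediate early list lies at 1.13 and the neutrophil list at -0.71, and at P70 the border-associated macrophage list lies at 1.00.

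Setting the OVA differences at P30 beside those at P70 asked whether the allergy group departed from its control in the same genes at both ages. The differences were close to uncorrelated across the 8815 expressed genes (r = 0.016, rho = -0.025; genes are not independent replicates). The immediate early genes Dusp1, Fos, Jun and Btg2 were higher in OVA at P30 by 3.31, 1.96, 1.99 and 1.71 and at P70 by 0.55, 0.17, 0.30 and 0.06. The class II genes H2-Eb1 and H2-Ab1 were lower in OVA at P30 (-0.71 and -0.59) and higher at P70 (2.21 and 1.71), as was Clec7a (-1.71 and 1.00). The difference of differences was largest for Hba-ps4 (3.18), H2-Eb1 (2.92), Clec7a (2.70), Ms4a7 (2.52), Pf4 (2.36) and H2-Ab1 (2.30). It was most negative for Dusp1 (-2.76), Cxcr4 (-1.89), Fos (-1.79), Jun (-1.69), Btg2 (-1.65) and the stefin-family gene Cstdc6 (-1.51). Cxcr4 at P30, Fos at P70 and in PBS at P30, and Cstdc6 in PBS at P30 and OVA at P70 lay under the floor, so the sizes and ranks of these 3 are uncertain.

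A set of 18 genes was at least 1.5-fold away from PBS in the same direction at both ages. The 12 that were higher in OVA, where independent lists would share 2.28, were Ccl3, Ccl4, Ccl12, Il1a, H1f2, Ttr, Ftl1, Erdr1, Hspb3, Mid1, Lipo3 and AI504432. Among them were 3 chemokine genes and the interleukin gene Il1a, at 0.76 at P30 and 0.64 at P70. The 6 that were lower, where 0.964 would be shared, were Mmp8, Retnlg, Naip6, Il1f9, Cst10 and Hbb-bh0. A further 14 genes were lower at P30 and higher at P70 (3.12 expected): Clec7a, Fcgr4, Gpr84, H2-Ab1, H2-Eb1, Hba-ps4, Lilrb4a, Lyz1, Mif, ND2, Plek, Ppp6c, Selenot and Slamf9. Cstdc6 alone was higher at P30 and lower at P70 (0.705 expected). The expected numbers treat all genes as equally likely to differ, so they are no baseline for chance. The 14 genes that were lower at P30 and higher at P70 exceeded their number as well. Members of these sets outside the rule for named genes were named after their values were seen, and the 15 genes with opposite directions numbered 9 after such centring of each array.

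**Figure D2:**
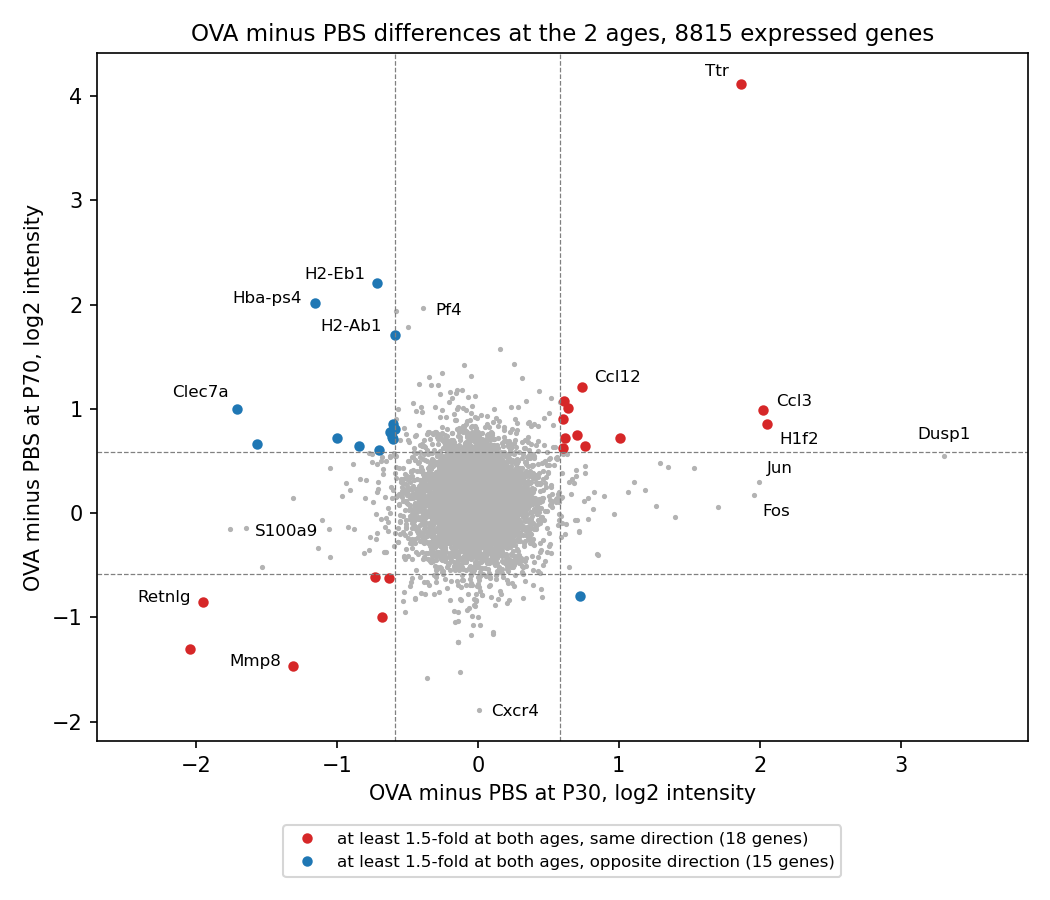
OVA minus PBS difference in log2 intensity at P30 (x axis) and at P70 (y axis) for each of the 8815 expressed genes; dashed lines mark 1.5-fold. Red points are the 18 genes beyond 1.5-fold in the same direction at both ages and blue points the 15 beyond it in opposite directions, such as Clec7a at -1.71 and 1.00.

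**Figure D3:**
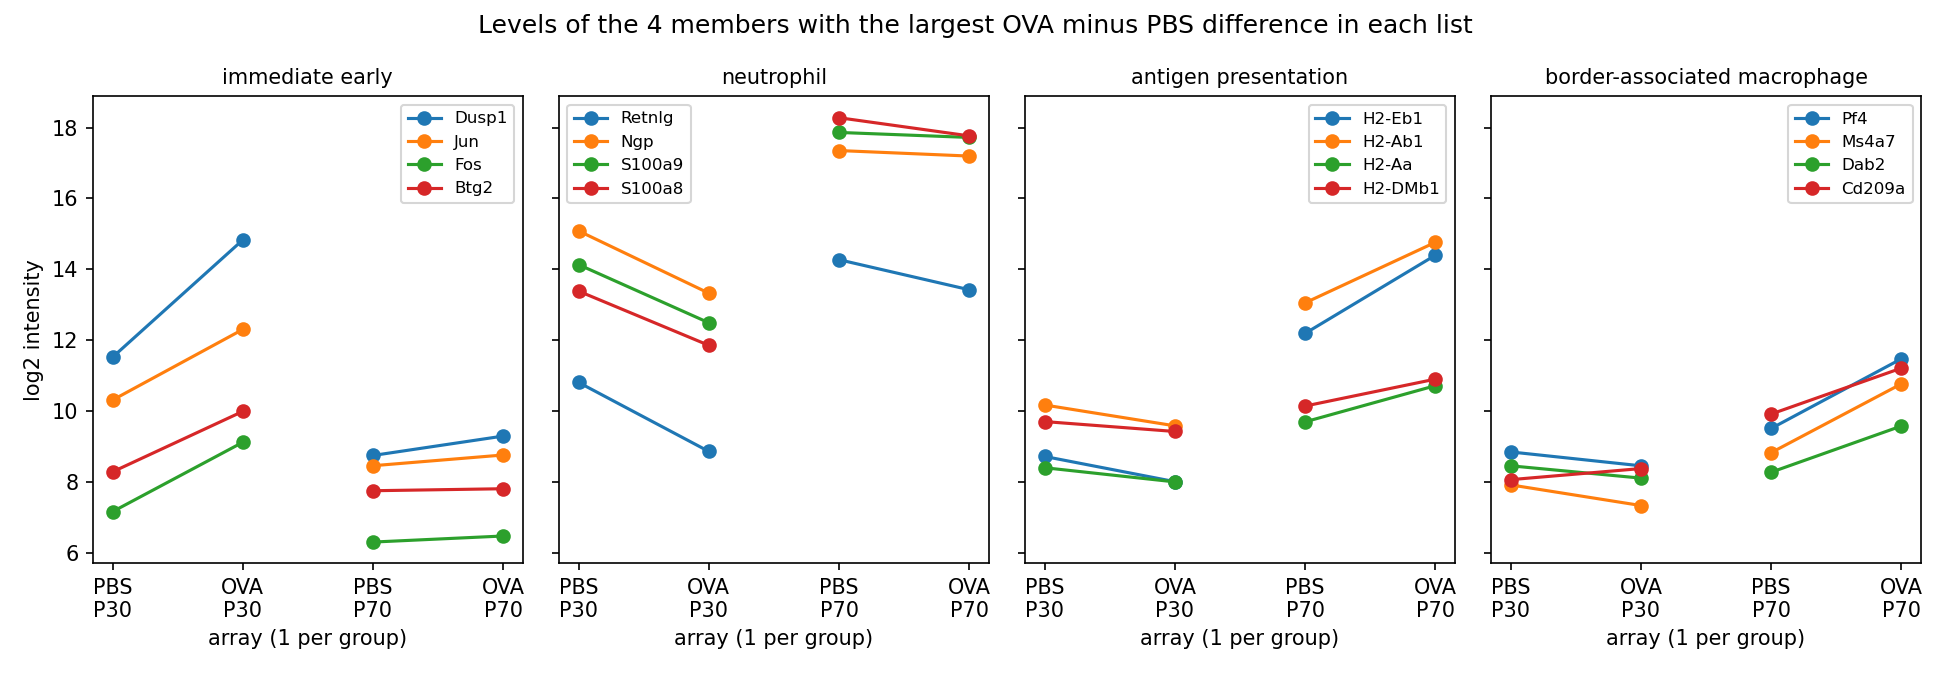
Log2 intensity (y axis) on each of the 4 arrays (x axis) of the 4 members with the largest OVA minus PBS difference in the immediate early and neutrophil lists at P30 and in the antigen presentation and border-associated macrophage lists at P70; each point is 1 array and lines join the arrays of 1 age. S100a8 lies at 13.38 and 11.85 at P30 and at 18.28 and 17.77 at P70.

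The comparison of P70 with P30 within each treatment set the arrays of the 2 ages against each other. Genes of neutrophils and monocytes were far higher at P70 in both treatments, and immediate early genes were lower. The P30 and P70 arrays also differed by a shift that depended on the level and in the number of probe sets at the upper limit (98 and 109 against 19 and 13), so a technical difference between them cannot be separated from age. The median difference of all expressed genes was 0.26 in PBS and 0.39 in OVA, and grew with the level, from -0.032 among the dimmest 10% of genes to 0.91 among the brightest in PBS and from -0.070 to 1.15 in OVA, so age differences are given here after subtracting the median. In PBS, the largest positive differences were those of Camp (5.05), S100a8 (4.64), the monocyte gene Ly6c2 (4.11), the mitochondrially encoded ND3 (3.92) and Mmp8 (3.53). In OVA they were those of Camp (6.38), H2-Eb1 (6.00), S100a8 (5.53), ND3 (4.98) and S100a9 (4.85). The largest negative ones in PBS were Dusp1 (-3.03), Sly (-2.76), Fau-ps2 (-2.33), Speer8-ps1 (-2.16) and Jun (-2.11), and in OVA Dusp1 (-5.92), Jun (-3.93), Sly (-3.69), Speer8-ps1 (-3.18) and Btg1 (-3.04). Sly, Fau-ps2 and Speer8-ps1 have near-identical copies and are uncertain.

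After subtraction of the median, 1631 genes were at least 1.5-fold higher and 630 at least 1.5-fold lower at P70 in PBS, and 1829 and 1131 in OVA; as deposited the counts were 2564 and 259, and 3406 and 388. The share of higher genes was 90.8% in PBS and 89.8% in OVA as deposited, 67.5% and 57.9% after centring each array on its median, 57.0% and 55.0% after centring along the level and 53.6% and 51.5% after quantile normalization. Relative to the median, the neutrophil list had a median of 2.01 in PBS and 2.84 in OVA, and the monocyte list of 0.92 and 0.93, each above all of its level-matched random lists. The immediate early list lay at -0.77 and -1.81, below all of its random lists. Oxidative phosphorylation lay at 0.77 in PBS and 0.76 in OVA and antigen presentation at 0.83 and 0.95, above the central range in both; centring along the level instead gave 0.53 and 0.41, and 0.43 and 0.43. T and NK cell markers lay at -0.53 and -0.81, below it in both, and at -0.53 and -0.51 after centring along the level. This list had 6 expressed members. As deposited, 1 was at least 1.5-fold higher and 1 lower in PBS, and 2 were higher and 2 lower in OVA. Homeostatic microglia genes lay at -0.12 in PBS and -0.062 in OVA, below the range of random lists from the same bins of level. The bins match brightness only in part: the median level was 13.01 for this list and 12.08 for the brightest 10% of genes. Members of this list also followed the arrays' upper limits: Cst3, Cx3cr1, Fcrls and Selplg in PBS and Cst3, Cx3cr1 and Sparc in OVA. Without them the medians were 0.080 and 0.15, still below the range (percentiles 0.835 and 0.360), and -0.44 and -0.40 after centring along the level, with 10 of 25 and 8 of 26 members at least 1.5-fold lower. The neutrophil list lay at 1.59 and 2.44 after such centring. Complement and phagocytosis (-0.063, or 0.00068 without C1qb) and cholesterol and lipid efflux (-0.36) lay below the range in PBS alone; before subtraction the latter had a median of -0.10 and a mean of 0.0015, and border-associated macrophage genes above it in OVA alone (0.74, against -0.12 in PBS). In all, 9 of 21 lists lay outside the range in PBS and 8 in OVA. The age differences in PBS and OVA share no array and correlated at r = 0.879 (rho = 0.857) across genes, which includes the shift that both have in common.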

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

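The tests of explanations in this part were chosen after the results were seen; the alternative settings were planned. Genes and lists whose OVA minus PBS difference had opposite signs at the 2 ages stand first; with 1 array per group the difference between the ages was not tested. Beyond 1.5-fold, 15 genes went opposite ways. Among the genes named by rule, the OVA effect at P70 exceeded that at P30 by 3.18 for Hba-ps4, 2.92 for H2-Eb1, 2.70 for Clec7a, 2.30 for H2-Ab1 and 2.24 for ND2, and lay below it by 1.51 for Cstdc6 (a difference of -1.51). H2-Ab1 was only just beyond 1.5-fold at P30 (-0.59) and short of it after lowess centring (-0.54). The border-associated macrophage list went from below the central range of random lists at P30 to above it at P70, with medians differing by 1.15, and the disease-associated microglia list likewise, by 0.42. Both P30 medians came inside that range with all probe sets of 1 symbol, and the disease-associated median at P70 did so after lowess centring, after quantile normalization and with the stricter filter.

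Probe sets outside the genes analysed, most of them without a single gene symbol, also differed. Of 19453 such probe sets at or above the floor, 677 were at least 1.5-fold higher in OVA than in PBS at P30 and 957 lower, and 1157 were higher and 3451 lower at P70. They were not named and no explanation was tested.

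Immediate early genes were higher in OVA at P30, with a list median of 1.13. A difference in scaling between the arrays is argued against, since centring along the level left the median of the same 14 genes at 1.13. Enzymatic dissociation of brain tissue is known to raise such genes in microglia, and of the other genes known for this, 7 were expressed: their median difference was 0.71, with 5 at least 1.5-fold higher (H1f2, Ccl3, Rgs1, Ccl4 and Nfkbiz), Txnip at 0.37 and Hsp90aa1 at -0.0051. A pool that was handled longer could give this, and so could a response in the animals; with 1 isolation per group the explanations cannot be told apart. The 3 genes Ccl3, Ccl4 and Nfkbiz also stand in the inflammatory list. H1f2, Ccl3 and Rgs1 were already among the 12 highest genes at P30, so the median of 0.71 is not independent of the pattern. At P70, where no immediate early gene was at least 1.5-fold higher, Ccl3 (0.99), H1f2 (0.86) and Ccl4 (0.75) still were.

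Neutrophil genes were lower in OVA at P30. Of the 8 list members with a mean level of 10 or more, 7 were at least 1.5-fold lower, all but Csf3r (-0.12). These are the genes of the pattern itself, so fewer neutrophils in the OVA pool and lower expression per cell cannot be told apart from them. More blood left in the PBS pool could lower them too; monocyte markers had a median of 0.017, but of 11 only Ly6c2 (0.25) stood at least 1 log2 unit above the floor in PBS, too few to decide. The globin genes Hba-ps4 (-1.16) and Hbb-bh0 (-0.73) were lower too, as blood would need, but have near-identical copies, and Slc25a37 differed by -0.18. At P70 Hba-ps4 was at 2.02 and Hbb-bh0 at -0.61, so these globin genes did not move together. How many neutrophils each pool held, and whether the treatment changed it, stays open and untested.

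Border macrophage genes were higher in OVA at P70. Scaling between the arrays is argued against, since the list median was 0.92 after centring along the level. Of the 6 markers at least 1 log2 unit above the floor in PBS, 5 were at least 1.5-fold higher (Pf4, Ms4a7, Mrc1, Dab2 and Cd209a), the exception being Maf (0.30), whose high level of 15.96 in PBS could hide a small share. These are the genes of the pattern itself, so more border macrophages in the OVA pool and higher expression of these genes in microglia after OVA cannot be told apart from them. Some markers of other cells were also higher in OVA at P70: Ttr of the choroid plexus by 4.12 and the monocyte list by a median of 0.30. So were 2 of 4 astrocyte markers, Ndrg2 by 0.89 and Slc1a3 by 0.70. Ttr was the sole expressed gene of its list, and the monocyte list came inside the central range after centring along the level. Other list medians were 0.18 for B cell, 0.061 for oligodendrocyte lineage, 0.041 for neutrophil and -0.0053 for T and NK cell markers. They were -0.091 for neuron, -0.12 for endothelial and mural and -0.28 for mast cell, basophil and eosinophil markers. Slc25a37 of the erythroid list differed by 0.24. Of the globin genes, Hba-ps4 was higher in OVA (2.02) and Hbb-bh0 lower (-0.61), and both have near-identical copies. Carry-over of other tissue or cells was not tested, and all of these explanations remain open.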

How the results depend on the processing

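The settings were chosen before the data were examined, except the 2 named in the methods as added later. All 24 genes named for the OVA comparison at P30 and all 24 at P70 kept their direction and stayed beyond 1.5-fold in each of the 9 settings that held them. Only median centring, lowess centring and quantile normalization could change these differences. The other settings changed which genes entered or averaged probe sets, and no named gene had more than 1 probe set. These genes were also picked for having the largest differences. The immediate early and neutrophil lists at P30, and the border-associated macrophage, type 2 and inflammatory lists at P70, stayed outside the central range in all 13 list settings; the other 5 lists at P30 and 3 at P70 did not. Genes with a mean level under the floor, which was set at the median of such means, were left out of the counts. The floor was not compared with a measure of background. No paired analysis was possible because each group had 1 array, so that the groups compared share a single replicate number.

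Counts moved as follows; apart from the thresholds and the numbers of genes entered, the cause was not tested. Genes beyond the threshold numbered 135 at P30 and 462 at P70 for OVA minus PBS, and 2823 in PBS and 3794 in OVA for age. With a 2-fold threshold they numbered 32, 58, 1261 and 1887. With all probe sets of 1 symbol, which added the gene classes otherwise left out, they numbered 583, 1625, 5964 and 7423. Quantile normalization gave 210, 207, 1873 and 2176. Lowess centring gave 1791 and 2127 for age, and no filter gave 205 at P30. The 18 genes with the same direction at both ages numbered 3 at 2-fold and 106 with all probe sets; the 15 with opposite directions numbered 1 and 72, and 9 with median or lowess centring. Lists outside the central range numbered 3 in place of 7 at P30 with all probe sets, and at P70 10 in place of 6 with the highest-array filter, 10 with the list mean and 15 with no filter. Among lists outside the central range, signs turned for the inflammatory list at P30 (-0.012) and the cholesterol list for age in PBS (0.075) with the stricter filter, and for the latter with the list mean (0.0015). For age, the scalings take away the shift of all genes, and signs turned with lowess centring, median centring and quantile normalization, in that order, for the complement list in PBS (-0.21, -0.10, -0.26) and the homeostatic list in PBS (-0.54, -0.16, -0.57) and OVA (-0.44, -0.094, -0.51).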

Other observations

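A set of 7 gene families was chosen after the values were seen, most of them because a member was among the genes named above, so their medians are descriptive. Without the named members, the medians were -0.92 for Naip and 0.41 for histone genes at P30, and 0.27 for Ms4a, -0.13 for Clec4 and -0.56 for Speer genes at P70. At P70, the interferon-inducible Ifi200 family, sensors of nucleic acids, had a median OVA minus PBS difference of 1.00 over 6 expressed members, with Ifi207 (1.24), Ifi204 (1.23), Ifi211 (1.10) and Mndal (0.89) at least 1.5-fold higher and Aim2 at -0.023. The median was 0.85 after lowess centring and 0.75 after quantile normalization, whereas the fixed interferon response list lay inside its central range. At P30 the same family had a median of -0.17. Members of this family are similar in sequence, so their probe sets can share signal.

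At P30, all 4 expressed Naip genes, which encode sensors of bacterial proteins, were lower in OVA: Naip6 (-2.04), Naip3 (-1.05), Naip5 (-0.92) and Naip2 (-0.44), with medians between -1.12 and -0.96 under the scalings tried. At P70 their median was -0.29, and it was -0.43 after lowess centring. These genes are near-identical copies. Histone genes had a median of 0.58 at P30 over 9 members, H1f2 (2.05) and H2bc21 (0.82) being the highest and H3c7 (-0.77) the lowest, and the median stayed at or above 0.58 under each scaling tried; at P70 the median was 0.37, and 0.22 after quantile normalization. All 8 expressed Speer genes, a family known from testis, were lower in OVA at P70, with a median of -0.63, -0.67 after lowess centring and -0.59 after quantile normalization. Speer genes are near-identical copies too, so their probe sets can share signal and are uncertain. All 8 were also lower at P70 than at P30 in PBS. The Ms4a family, to which Ms4a7 belongs, had medians of -0.098 at P30 and 0.32 at P70 over 7 members, the latter 0.17 after lowess centring. The Clec4 family, to which Clec4b1 (1.58 at P70) belongs, had medians of -0.11 and -0.10 over 8 members, with 5 of them lower in OVA at P70. The 3 mitochondrial ND genes had medians of -0.068 and 0.73. The proliferation gene Mki67 was 2.34-fold higher in OVA at P70 (9.79 against 8.56), and Stmn1 1.82-fold higher, while Pcna, the brightest cell cycle gene, differed by -0.072.

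Ttr had the largest OVA minus PBS difference at P70, and the other 13 genes of the ependymal and choroid plexus list found on the array had mean levels under the floor; Kl, Clic6 and Folr1, for example, lay between 5.23 and 6.34 on all 4 arrays.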
